A study of Mus musculus with 2 samples.

How the data were processed

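DNA methylation was measured by bisulfite sequencing of target-enriched libraries (mouse SureSelect Methyl-Seq) from the hippocampus of C57BL/6 mice. Bisulfite turns unmethylated cytosine into uracil, which is read as T. The share of C among the C and T calls at a cytosine is therefore taken as its methylation level. Other forms that resist bisulfite, such as hydroxymethylated cytosine, would count as methylated and were not told apart. There were 2 libraries, 1 from an untreated control and 1 from offspring exposed to 5000 ppb arsenic trioxide (ATO) in drinking water. Per the labels' protocols, exposure ran from before mating until lactation and went on in the offspring after weaning. The labels do not say whether a library came from a single animal or a pool.

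The submitters' processing notes name bcl2fastq, Bismark 0.19.0 (a bisulfite aligner and methylation caller) and Bowtie2, and the mouse build mm9. Read trimming, duplicate removal, coverage filters and the tool that wrote the tables are not given in the sources used here. Each deposited table lists CpG cytosines by strand with 2 kinds of value. Per the file headers, the coverage is the raw count of reads with a C or T call, and the other columns give C and T as a percent of that coverage. The percent values were deposited with 2 decimals. Methylated counts were recovered as coverage times percent C, rounded to a whole number. In both libraries 100% of these products were whole within the 0.005 percentage points of rounding. At coverages above 10000 reads, which occurred at 72 cytosines of the control and 60 of the ATO library, the count is not fixed to the single read. If duplicates were not removed, reads at a cytosine are not independent molecules, so intervals and exact tests cover counting error only.

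A cytosine was analysed where its coverage was at least 10 in both libraries, which kept 2312276 of the 7818148 listed in either library and left a median coverage of 41 in the control and 44 in the ATO library. Strands were kept apart as deposited, and 95.2% of analysed cytosines lay on the reverse strand. A difference is ATO minus control, in percentage points. Single cytosines were compared with a two-sided Fisher's exact test and Benjamini-Hochberg adjustment over all tested cytosines. A cytosine was called at an adjusted p under 0.05 with a difference of at least 25 points. Bins of 500 bp with at least 5 analysed cytosines were compared on summed calls. Because calls on the same fragment are not independent, each sum was first divided by the largest number of analysed cytosines in any 300-bp stretch of the bin. A bin was called at an adjusted p under 0.05 with a difference of at least 20 points. With 1 library per group these tests compare the 2 libraries, not the conditions, and no test of the exposure is possible. Level classes used the mean of both libraries, so that neither library defined them. Intervals on mean differences are 95% percentile intervals from 1000 bootstrap draws of 1-Mb blocks. They describe variation along the genome, not between animals. Exact binomial (Clopper-Pearson) 95% intervals were given for levels of a library, and for bins they were computed on the divided sums.

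The number of calls that read counting error alone would give was taken from counts redrawn from the binomial at the pooled level of each cytosine. It leaves out variation between molecules and between animals, so it is not the number expected between unexposed libraries. It is given for cytosines alone, since redrawn cytosines are independent and the division of bin sums would then hold bin calls far below chance. The excess of differences over counting error was expressed as a dispersion, the mean squared standardised difference at cytosines between 20 and 80%, which is close to 1 under counting error alone. It was also measured between the 2 strands of the same CpG within a library. The callers were tested on simulated data with the real depths and 200 changed bins. Of bins changed by 50 points, 82.0% were recovered, and of bins changed by 30 points 15.6%. Of cytosines in them, 71.2% and 20.2% were recovered at 50 and 30 points. There were no false bin calls, and 8 and 2 false cytosine calls. Simulated cytosines are also independent, so the division of bin sums left little room for false bin calls, and their absence is no check. Few bins were changed, so the adjusted threshold was stricter than in the measured data.

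Before the data were examined, the tests of cytosines, bins and overall level, their thresholds, the gene lists and most alternatives were fixed. The tests that weigh explanations were set later, after the patterns had been noticed, and those of conversion, of shuffled runs and of matched bins after their results had been seen. The planned promoter and gene list comparisons (imprinted, germline, synaptic, immediate early, methylation machinery, oxidative stress, stress hormone, Hox, protocadherin and cell type marker genes) need gene positions in mm9. The gene table used here is on GRCm38.p6, so no gene was assigned to any region and these comparisons were not analysed here. The rule for regions named in the text was therefore the 5 called bins with the largest change in each direction. Runs of called bins, 1-Mb windows and the split of bins by distance to unmethylated CpG-dense bins were chosen after the values were seen. Bins had by then also been split by level, CpG density and chromosome, so the split by distance is the one kept from several that were looked at. The runs and windows named were likewise picked by their size. Whether changes at isolated single cytosines came from sequence variants was looked at informally and not tested. Coordinates are 1-based mm9 positions. Alternatives covered the coverage minimum, strands, depth, chromosomes, thresholds, bin size, the divisor, the test and the dispersion. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and numba 0.67.0, and plots used matplotlib 3.10.9.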

Results

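CpG methylation was measured in the hippocampus, a brain region needed for memory, of 1 control mouse library and 1 library from offspring exposed to arsenic trioxide through development. The control library held 135987272 C or T calls at 5772100 CpG cytosines, and the ATO library 147924810 calls at 5973197 cytosines. In both, most listed cytosines were shallow, with medians of 5 and 4 reads. Cytosines with at least 10 reads made up 42.5% and 41.8% of those listed and held 93.7% and 94.0% of the calls. The reverse strand held 92.7% of calls in each library. Both libraries carried reads on chromosome Y, with medians of 35 and 38 reads at 192 analysed cytosines. On chromosome X the median coverage was 26 in the control and 29 in the ATO library, against 41 and 45 on the autosomes. CpG-dense bins of X, with at least 15 analysed cytosines, had a median level of 2.35% in the control and 2.34% in the ATO library, near the autosomal 2.82% in each. No group had a replicate, so every difference below compares these 2 libraries and has no replicate check.

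The series asks whether developmental arsenic exposure changes DNA methylation in the hippocampus. Methylation was lower in the ATO library. Over 2312276 cytosines the mean level was 38.0% in the control and 36.7% in the ATO library, a difference of -1.28 points (95% block bootstrap interval -1.34 to -1.22, SD of the differences between cytosines 11.9). Over all calls of each library 41.52% (exact 95% interval 41.51 to 41.53) were methylated in the control and 40.31% (40.30 to 40.32) in the ATO library. The share of cytosines above 90% was 15.9% in the control and 14.5% in the ATO library. The share below 10% was 43.6% and 44.2%. Each of the 19 autosomes had the lower mean in the ATO library, with differences from -0.94 points on chromosome 13 to -1.60 points on chromosome 4. Across cytosines the levels of the libraries correlated at a Pearson r of 0.95, although cytosines are not independent replicates.

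In percentage points, the fall was largest in partly methylated DNA, smaller in highly methylated DNA and not seen in bins below 5%. Percent levels are bounded, and the SD of the differences was also largest at 40 to 60%. It was 14.5 there, 6.69 between 80 and 90% and 3.75 between 90 and 95%. The sizes in points therefore do not show that partly methylated DNA was affected more than highly methylated DNA. In 500-bp bins with a mean level between 40 and 60%, methylation averaged 52.3% in the control and 48.3% in the ATO library, a difference of -4.01 points (interval -4.30 to -3.72, SD 14.5, 17871 bins). Bins between 60 and 80% differed by -3.48 points and bins between 20 and 40% by -2.27 points. Highly methylated bins were lower too, with differences of -1.96 points between 80 and 90% (interval -2.06 to -1.86, 18519 bins) and -0.94 points between 90 and 95% (interval -1.02 to -0.87). At 95% and above the difference was -0.30 points, and below 5% it was 0.04 points (interval 0.02 to 0.05). Partly methylated bins were most frequent among bins with few CpGs. Of bins with 5 to 7 analysed cytosines 51.4% lay between 20 and 80%, and these differed by -3.42 points. Of bins with 31 to 50 cytosines 4.11% lay in that range, and these differed by -1.60 points (interval -2.62 to -0.54). The 101 partly methylated bins with 51 or more cytosines differed by 1.06 points, with an interval from -0.60 to 2.83.

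**Figure D1:**
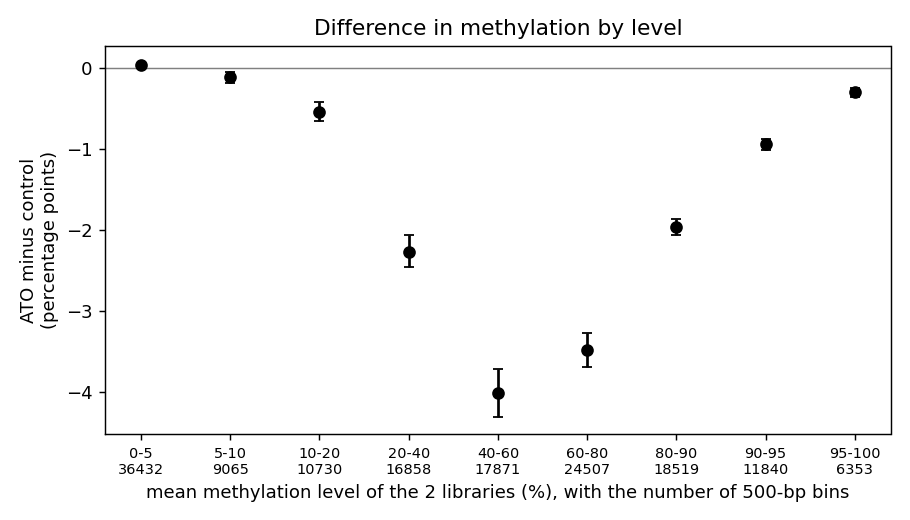
Mean difference in methylation, ATO minus control in percentage points, of 500-bp bins grouped by the mean level of both libraries in percent; the number of bins is given under each class and bars are 95% block bootstrap intervals along the genome. The difference is largest at 40 to 60%, at -4.01 points, and near 0 at both ends.

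Position relative to unmethylated CpG-dense DNA separated the bins further. The 28441 bins with at least 15 analysed cytosines and a mean level under 10%, the pattern typical of CpG islands, averaged 2.84% in the control and 2.85% in the ATO library. Partly methylated bins within 2000 bp of such a bin, 12380 in number, differed by -0.77 points (interval -1.02 to -0.50). The 46856 partly methylated bins farther away differed by -3.96 points (interval -4.15 to -3.77). Remote bins drawn to match the flanking bins in level and number of cytosines differed by -3.80 points on average. Over 200 draws they differed by -4.07 to -3.52 points, all beyond the flanking value. Bins with 20 or more cytosines were matched as 1 class, and depth was not matched. Among the called bins described next, 185 of 321 in the flanks (57.6%) were higher in the ATO library, against 778 of 2411 elsewhere (32.3%). Calls were rarer in the flanks, at 1.03% of bins against 2.61% of remote bins. Among partly methylated bins, 180 were called higher and 133 lower of 12380 in the flanks. Of the 46856 remote ones, 754 were called higher and 1574 lower. Gains were thus not more frequent among flanking bins, and losses were rarer there. A two-sided Fisher's exact test of direction by position gave p = 4.3e-18. Neighbouring bins are not independent and the split was chosen after the values were seen. This p therefore cannot be taken at face value even for these 2 libraries, and it is no test of the exposure.

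At single cytosines, 61225 of 2312276 (2.65%) were called with Fisher's exact test and Benjamini-Hochberg adjustment. Of these, 40035 were lower and 21190 higher in the ATO library, so 65.4% of calls were losses. In 500-bp bins, 2732 of 152175 (1.80%) were called, 1769 lower and 963 higher. Each of the 19 autosomes had more lower than higher bins. Lower bins had a median level of 72.6% in the control and 41.0% in the ATO library. Higher bins had medians of 42.0% and 74.7%. Full losses or gains were uncommon. Of the lower bins, 178 (10.1%) ended under 20% in the ATO library, and of the higher bins 49 (5.09%) were under 20% in the control. Nearly all of these calls were lost with counts divided by the dispersion seen between the 2 strands of a CpG within a library. This left 1839 called cytosines, near balance at 947 lower and 892 higher, and 12 called bins (5 lower, 7 higher). Bin sums had already been divided for shared fragments, so for bins this was a second division, by a value measured at single cytosines. The divisor, 2.78, came only from CpGs covered on both strands. Between the libraries 0.74% and 0.99% of these were called, by strand, against 2.65% of all tested cytosines. The same divisor served all depths, although the dispersion between libraries rose from 2.28 at 10 to 19 reads to 9.03 at 160 or more. The calls left are therefore not a corrected count. Counts redrawn with read counting error alone gave 0 called cytosines, with 46144 (2.0%) at an unadjusted p under 0.05 by Fisher's exact test, against 295912 (12.8%) measured.

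Differences exceeded read counting error both between the libraries and inside each library. The dispersion between the libraries was 4.28, against 1.01 for redrawn counts. Between the 2 strands of the same CpG it was 2.70 in the control and 2.86 in the ATO library. At those same CpGs it was 3.07 between the libraries on the forward strand and 3.70 on the reverse strand. Of 61728 such CpGs, 352 were called between strands within the control and 456 within the ATO library, and 457 and 609 between the libraries on the forward and reverse strand. With counts divided by the dispersion between the libraries, 30 cytosines were called, 12 lower and 18 higher. That dispersion contains any real difference between the libraries, so dividing by it removes such differences by construction. When the median difference of partly methylated cytosines, -3.90 points, was removed, 56904 cytosines were called, of which 46.5% were lower, against 65.4% without its removal; a split near balance follows from this centring.

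The 5 bins with the largest losses lay on 5 chromosomes. The bin at chromosome 1, 9639001 to 9639500, fell from 96.5% (exact 95% interval 76.8 to 100) in the control to 19.7% (5.73 to 43.7) in the ATO library over 6 cytosines, with mean coverages of 14.3 and 20.3 reads (Fisher's exact test, adjusted p = 0.0028). The bin at chromosome 12, 107955001 to 107955500, had 98.1% in the control and 32.1% in the ATO library. The other losses were at chromosome 2, 162734001 to 162734500 (75.2% and 16.4%), chromosome 15, 97191001 to 97191500 (76.8% and 21.4%) and chromosome 13, 108713001 to 108713500 (83.9% and 30.1%). The largest gain, at chromosome 17, 47362001 to 47362500, went from 19.2% (8.19 to 36.0) to 83.8% (68.1 to 94.9) over 5 cytosines, with mean coverages of 36.4 and 33.4 reads (Fisher's exact test, adjusted p = 2.6e-05). A pair of bins on chromosome 5 were also higher, at 34581001 to 34581500 (24.5% and 84.3%) and at 23268501 to 23269000 (35.7% and 90.5%). The remaining gains were at chromosome 11, 55030501 to 55031000 (23.4% and 80.6%) and chromosome 13, 95896501 to 95897000 (32.2% and 88.7%). Over the 10 bins mean coverages lay between 13.8 and 49.5 reads, and adjusted p by Fisher's exact test lay between 2.6e-05 and 0.035. None of these 10 bins was called when counts were also divided by the dispersion between strands. This was a second division, after that for shared fragments. In the shallowest bins it leaves too few counts for any difference to be called, so the loss says little on these bins. No gene annotation of mm9 was used here, so their gene context is not given.

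Some called bins lay side by side. Called bins of 1 direction, with at most 2 bins between neighbours, formed 23 runs of 3 or more, 13 lower and 10 higher in the ATO library. Shuffling the calls among the bins of 20 to 80% gave at most 3 such runs in 1000 shuffles, against 20 among those bins as measured. The shuffles did not keep the depth, level or number of cytosines of called bins. The longest run, on chromosome 13 from 111187501 to 111192000, held 7 called bins, all higher. Of the 91 analysed cytosines in this 4500-bp span, 90 were higher in the ATO library and 47 were called. Its called bins averaged 32.4% in the control and 61.1% in the ATO library, with median coverages of 99 and 102 reads per cytosine in the span. The mean difference in the span was 25.1 points. The 3 analysed cytosines nearest to it, at 111187314, 111187338 and 111187438, were not called but were also higher, with 26.3%, 28.9% and 27.0% in the control and 45.8%, 45.5% and 51.7% in the ATO library. The edges of the run are thus those of the bins, and no cytosine was analysed within 2500 bp above it. Runs of 5 bins were higher on chromosome 13, 5863501 to 5866000 (26.8% and 61.7%), and chromosome 15, 68761501 to 68764000 (36.8% and 66.0%). A run of 5 was lower on chromosome 7, 38349001 to 38351500 (62.2% in the control and 32.4% in the ATO library), and runs of 4 were lower on chromosomes 10 and 3.

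**Figure D2:**
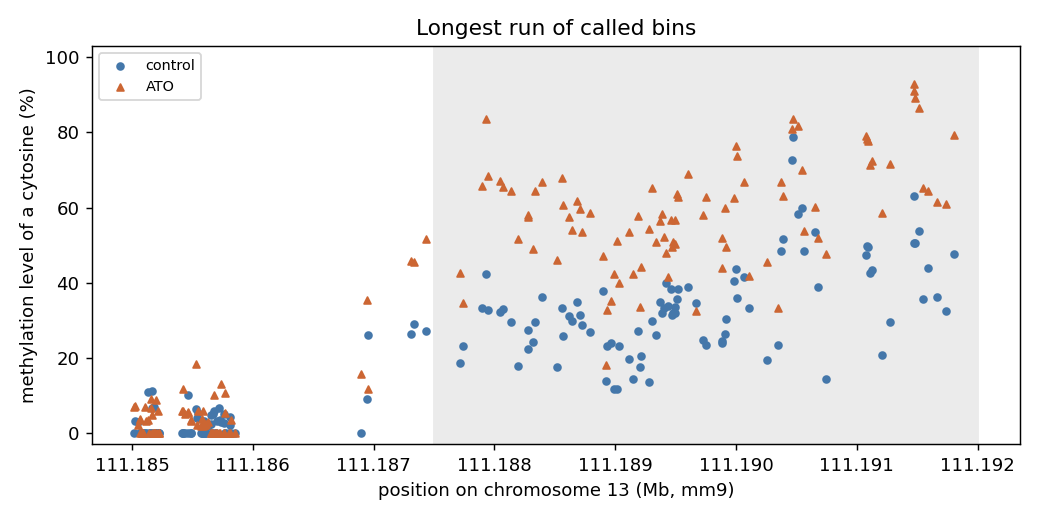
Methylation level in percent of each analysed cytosine, control (circles) and ATO (triangles), along mm9 chromosome 13 around the longest run of called bins (grey, 111187501 to 111192000). In the run 90 of 91 cytosines are higher in the ATO library, as are the 3 cytosines nearest to its left edge; the next 3 differ in both directions, and the unmethylated cytosines at the far left differ little.

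Differences of neighbouring cytosines were correlated, and more so the closer they lay. After the mean of each level class was removed, the differences of partly methylated cytosines within 50 bp of each other correlated at r = 0.64. At 200 to 300 bp r was 0.34, at 1000 to 2000 bp 0.15 and at 50000 to 100000 bp 0.026. In redrawn counts r was 0.0017 within 50 bp. These correlations are across pairs of cytosines in the 2 libraries, which are not independent replicates.

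**Figure D3:**
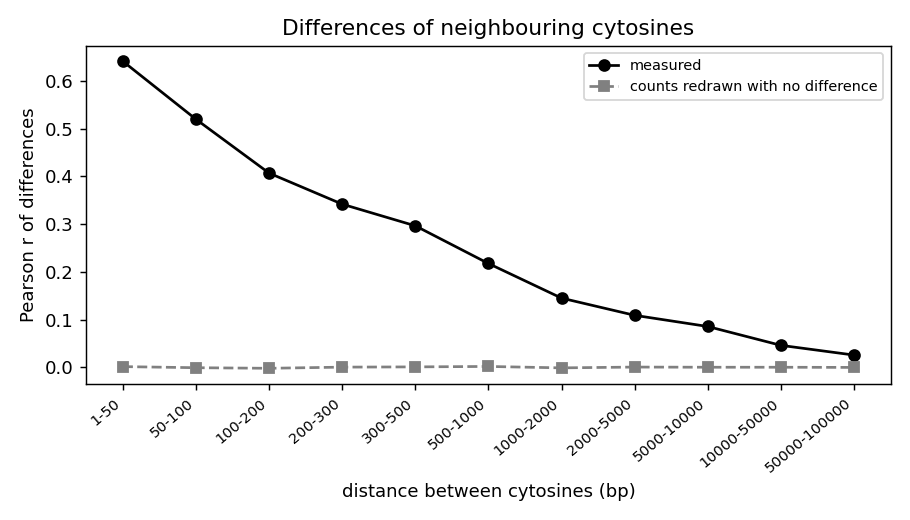
Pearson r of the difference in methylation between pairs of partly methylated reverse-strand cytosines against their distance in bp, as measured (circles) and with counts redrawn with no difference (squares, read counting error alone). The measured r falls from 0.64 within 50 bp to 0.026 at 50000 to 100000 bp, while the redrawn r stays near 0.

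Fewer bins were called on chromosome X than on the autosomes. Of 2439 X bins 5 were called (0.21%), against 1.82% of autosomal bins, where single chromosomes ranged from 1.11% on chromosome 7 to 2.24% on chromosome 18. Partly methylated bins made up 21.3% of X bins and 39.2% of autosomal bins. They differed by -2.04 points on X (interval -3.19 to -0.69) and by -3.31 points on the autosomes. Mitochondrial DNA read 1.97% methylated calls in the control and 2.06% in the ATO library. Of its 476 analysed cytosines 0 were called with Fisher's exact test.

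**Figure D4:**
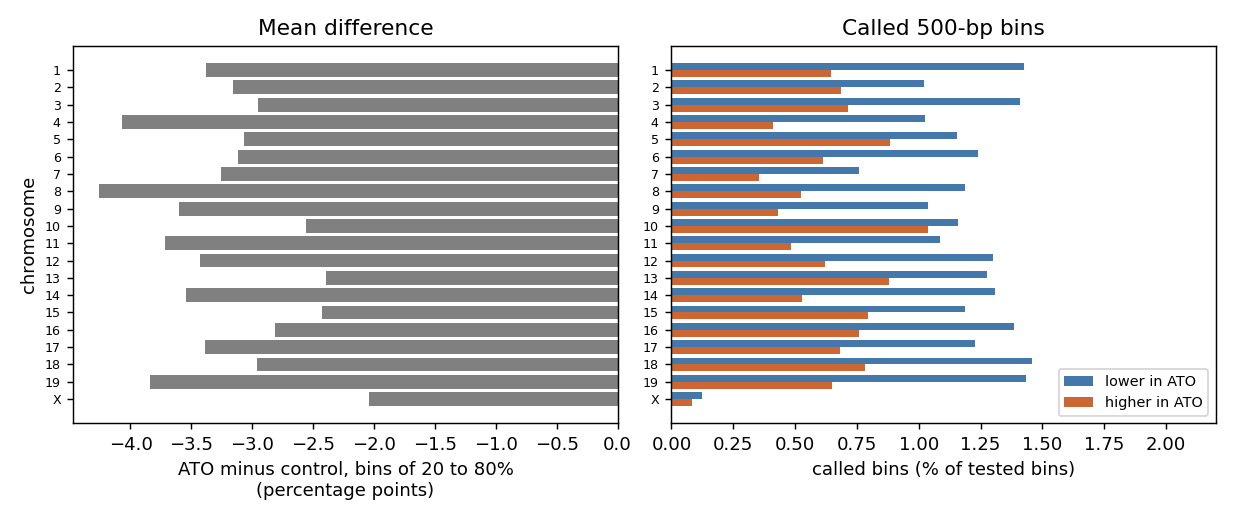
Left, mean difference of partly methylated bins (20 to 80%), ATO minus control in percentage points, per chromosome; right, called bins lower or higher in the ATO library as percent of tested bins. Every chromosome shown has a lower mean in the ATO library, and chromosome X has the fewest calls.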

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

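Most alternatives were fixed before the data were examined; division by a dispersion, partly methylated bins alone and the settings for position relative to dense bins were chosen after seeing the data. The mean difference of -1.28 points stayed negative under each of the 9 alternatives. It was -1.25, -1.33 and -1.35 points at coverage minimums of 5, 20 and 30, -1.20 points with each call weighted alike and -3.29 points in bins of 20 to 80% alone. The count of cytosines fell from 61225 to 39902 at an adjusted p under 0.01, to 1839 with counts divided by the dispersion between strands and to 30 with counts divided by the dispersion between libraries. The dispersion between libraries contains any real difference between them, so the fall to 30 follows in part by construction. The other settings for cytosines stayed within 1.5 times the main count. Lower calls outnumbered higher calls in 12 of 14 settings. Among these 12, division by the dispersion between strands was near balance, with 947 lower and 892 higher calls. That is 51.5% lower, against 65.4% in the main setting. The other 2 say little on direction: removing the median difference centres the calls by construction (46.5% lower), and the dispersion between libraries leaves 12 lower and 18 higher calls. The count of bins rose from 2732 to 5567 with 200-bp bins and to 7524 with all calls counted, and fell to 546 with at least 10 cytosines per bin and to 12 with counts divided by the dispersion between strands, too few to compare directions (5 lower, 7 higher). Lower bins outnumbered higher bins in the other 13 of 14 settings. Of 92 values of the 10 named bins under alternatives, 78 were still called, 14 were not and 0 reversed. Most named bins could not be tested under the stricter settings: 1 of the 10 had enough cytosines at a coverage minimum of 20, 0 at 30 and 1 with at least 10 cytosines per bin. The 14 were all 10 bins under division by the dispersion and 2 bins, on chromosomes 2 and 15, at a coverage minimum of 5 and after thinning. Bins near unmethylated dense DNA differed by -1.13 points with a flank of 4000 bp, and remote bins by -3.71 points at a coverage minimum of 20; the other settings stayed within the bootstrap intervals. The cause of these changes was not tested, except that division lowers the effective read number. With at least 10 cytosines per bin the tested bins fell to 66779, and the share called fell too, from 1.80% to 0.82%. In simulated data with the real depths and 200 changed bins, 15.6% of the bins changed by 30 points were recovered. So few changed bins make the adjusted threshold stricter than in the measured data, so this share does not measure the effect of depth alone. The promoter and gene list alternatives were not run, for want of an mm9 annotation. No paired analysis was possible because each group has 1 library.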

Other observations

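The tests of bisulfite conversion, of shuffled runs and of matched bins near dense DNA, and the 1-Mb windows, were chosen only after the result was seen; the other tests were set before their values were computed but after the patterns themselves had been noticed in the same data.

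Some 1-Mb windows differed from other bins of the same level; those named here are among the 6 most extreme of 1270 windows with at least 15 partly methylated bins. On chromosome 18 from 55000001 to 56000000, 25 partly methylated bins averaged 64.0% in the control and 42.7% in the ATO library. These bins lay in 17 stretches of 10 kb, of which 15 had the lower mean in the ATO library, and without the stretch that contributed most the difference was -20.8 points. On chromosome 1 from 62000001 to 63000000 (67.2% and 47.6%) 12 of 13 stretches were lower, and on chromosome 16 from 43000001 to 44000000 (65.6% and 46.1%) 16 of 17. Chromosome 10 from 98000001 to 99000000 averaged 48.1% in the control and 56.2% in the ATO library, with 22 of 31 stretches higher and a difference of 6.37 points without the stretch that contributed most. A window with many partly methylated bins, chromosome 18 from 37000001 to 38000000 with 213, read 51.4% and 52.9%, which was 4.87 points above bins of the same level, with 0 called in either direction.

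The lower level in the ATO library is the first pattern to follow up. Stronger conversion would lower fully methylated cytosines most, or low ones if the control were incompletely converted, yet the larger of the differences above 95% and below 5% was 0.061 of that at 40 to 60%, which argues against it. Amplification favouring unmethylated molecules predicts that evenly half-methylated bins fall too. These 252 bins differed by -4.71 points (interval -6.99 to -2.45, SD 16.8), 1.23 times the other bins of 35 to 65%. Of them, 25 were called lower and 12 higher. Any fall shared by partly methylated bins would also lower these bins. The result therefore cannot tell such a bias from other causes, and the bias stays open. A bias set by the methylation level alone is argued against by the flanks of unmethylated dense DNA, at -0.77 points against -4.07 to -3.52 in matched remote bins. One that also depends on base composition stays open, since base composition was not measured. The number of cytosines, which was matched in the flank comparison with 20 or more as 1 class, is no measure of it. Partly methylated bins differed by -3.42, -3.29, -3.07 and -3.24 points in classes from 5 to 20 cytosines. They differed by -2.42 and -1.60 points at 21 to 30 and 31 to 50, and by 1.06 points (interval -0.60 to 2.83) in the 101 bins with 51 or more. A difference in the mix of cell types stays open. Of partly methylated bins past 10 points 31.3% were higher, between the bounds set for and against it. That share depends on the mean difference of these bins, -3.29 points, and its SD of 12.5, whatever their cause. It therefore cannot decide on the mix of cell types. The exposure itself and differences between individual mice cannot be separated with 1 library per group.

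The second pattern is the excess of differences over counting error. At CpGs covered on both strands, the strands within a library showed 0.745 of the excess dispersion over 1 seen between libraries there (1.78 against 2.39). Few independent molecules behind the reads could give this. Over all partly methylated cytosines the excess between libraries was larger, at 3.28. The dispersion between libraries rose from 2.28 at 10 to 19 reads to 9.03 at 160 or more, as either limited molecules or real differences would give. Fragments alone would not link cytosines far apart, yet differences 500 to 1000 bp apart correlated at r = 0.218 across cytosine pairs and those 5000 to 10000 bp apart at 0.086, against 0.002 and 0.0004 in redrawn counts. Runs of 3 or more called bins as many as measured arose in 0 of 1000 shuffles. The shuffles did not keep depth, level or number of cytosines, and adjacent bins can share fragments. They therefore cannot decide whether differences are independent at each bin. A candidate explanation is therefore both at once, molecule sampling at single sites and regional differences between the 2 libraries, and which of the single calls belong to which cannot be read from 1 library per group.

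The third pattern is the low number of calls on chromosome X. Autosomal bins matched to the X bins in level, read number and cytosines gave a median of 13 calls, and 15 of 1000 draws had no more than the 5 on X, so lower depth and another mix of levels are unlikely to be the whole cause. The mean difference of X bins was -0.57 points (interval -0.93 to -0.25), against -1.36 to -0.85 in the matched draws, and these ranges overlap. No biological explanation was tested.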
